A study of Homo sapiens with 8 samples.

How the data were processed

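Polyadenylated RNA was measured in 8 libraries of MDA-MB-231 cells, in 4 groups of 2 given by the hairpin label (shSC or shCHD4) and the O2 level (20% or 1% for 24 hours). Per the labels' protocols, cells grew in DMEM with serum, RNA was isolated with a column kit and treated with DNase, and libraries were made with a KAPA mRNA kit. The submitters' processing notes name bcl2fastq 2.17, FastQC 0.11.2, TopHat, Picard 1.127, featureCounts, edgeR and the human build hg19. The gene annotation and the strand setting of the counting are not given in the sources used here.

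The deposited table is named as FPKM per gene, but its values are a signal proportional to reads, which the authors had divided by 1 factor per library and not by gene length. In each library 100% of values were whole multiples of 1 step within a tolerance of 0.01 reads, and the library totals of the deposited values ran from 975172 to 1076118. They are called normalised read counts, and the whole reads were recovered by dividing by the step. The recovered totals ran from 24947627 to 31903585 reads per library, and the 10 most abundant genes took 4.04% to 5.02% of them. The choice of tests had assumed FPKM, with edgeR named beforehand in case the table held raw counts. The test chosen for such values was kept, and count tests on the recovered reads were added as alternatives. No correction for length was made, so levels of different genes are not compared, except to pick members by read count, which favours long genes.

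The table held 19583 rows, of which 27 had names that a spreadsheet had turned into dates and 2 were repeated names. These rows were kept in the tests without being named. Among the tested genes 21 had values identical to those of another gene. For chromosomes, gene order and current names, 17289 of 19581 distinct names matched a RefSeq symbol and 1522 a synonym, 770 did not match, and 96.1% had a chromosome. That reference and the GENCODE transcripts used for GC content and length (94.8% of names) are of another build than the table's, so no coordinates are given.

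Genes with a mean of at least 1 over the 8 libraries, 12645 in all, were tested with limma 3.58.1 in R 4.3.3 on log2(value + 0.5), in 1 fit of the 4 group means with a variance trend (4 residual and 13.9 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The 4 groups share an estimate of the spread because each has 2 libraries. The 5 comparisons were 1% against 20% O2 under each label, shCHD4 against shSC at each O2 level, and the interaction. Fold changes are on the log2(value + 0.5) scale and understate the change of low genes. An exact permutation test of 2 against 2 libraries cannot give p below 0.33 and was not used. Intervals are at 95%, and cover the spread between these libraries.

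Gene lists, 26 in all, were fixed before the data were examined, as were the tests, most of the alternatives and the rule for naming genes. By that rule the text names the 10 largest rises and falls for 1% O2 under shSC and for each label comparison, the 3 largest each way for 1% O2 under the shCHD4 label and the 6 largest each way for the interaction, among genes past the threshold with a mean of at least 2 in the highest group and, outside the interaction, no overlap between the groups. It adds CHD4, and for each list described up to 4 members with the smallest p, plus the member with the highest mean count over the 8 libraries where most did not pass. CDK2AP1 and the genes named as the only member of a list against its direction were chosen after their values were seen. Which lists were described with named members, the analysis of neighbouring genes with its limit of 0.3, and the added alternatives were chosen after the data were seen.

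Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 115 tests, of which 61 passed. With an estimated correlation 10 of these passed, in the same direction: the HIF target, angiogenic and invasion lists under both O2 comparisons, the interferon list under O2 in shSC and in the interaction, and the inflammatory list at both O2 levels between labels. That version also rests on the 4 residual degrees of freedom, so a lost call does not measure correlation alone. Between labels at 20% O2 the inflammatory list had an estimated correlation of -0.021, under the preset 0.01. Its camera adjusted p still went from 3.83e-16 to 0.0271. Estimated correlations ran from -0.073 for neuronal genes to 0.859 for ribosomal protein genes. They were 0.501 for the cell cycle, 0.491 for the respiratory chain, 0.439 for glycolysis and 0.253 for collagen modification. For such lists the preset 0.01 is far lower than the estimate, so p-values at the preset can be much too small. The rotation test fry, which asks whether a list moves 1 way on balance without comparing it with other genes, passed 79. None of the 13 mitochondrially encoded genes is in the table.

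Genes raised by 1% O2 under shSC share libraries with the label comparison, so 50 sets of libraries with no label difference were simulated from the fitted means. Neighbouring genes were grouped in gene order along autosomes, 40 or more to a group, using 10250 genes with a mean of at least 5, and compared with 1000 permutations of gene order.

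Alternatives were pseudocounts of 0.1 and 1, no filter or a minimum mean of 5, median-ratio scaling, quantile normalization, no variance trend, the compared groups alone, the replicate number as a block, a 2-fold minimum, leaving out each library, other choices of hypoxia-induced genes, and an estimated correlation or fry for lists. Added were edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, and centring of each library on the running median of 41 neighbouring genes. The edgeR test called 4490, 2959, 9570, 9861 and 563 genes in the 5 comparisons in the order above and DESeq2 3347, 1977, 8833, 9072 and 386, with limma sharing 4313, 2788, 9465, 9749 and 519 of the former and 3337, 1973, 8824, 9071 and 371 of the latter in the same direction. DESeq2 gave no adjusted p for 981 genes for O2 under the shCHD4 label and 1962 in the interaction.

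The fit was tested on simulated data with 50 genes changed by each size. At 1.5-fold it recovered 92% and 98% for O2 under shSC and the shCHD4 label, 84% and 82% for the label at 20% and 1% O2 and 76% for the interaction, and at 2-fold 98%, 96%, 98%, 98% and 96%. Between 6 and 12 unchanged genes were called per comparison. A simulated list change was called in 3 of 3 tests and in 0 of 112 others, and 3 raised groups of neighbouring genes had a median of 0.304 against at most 0.029 elsewhere. Genes were simulated independently of each other. False calls for lists or neighbouring genes that vary together in real libraries were therefore not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.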

Results

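RNA was sequenced from MDA-MB-231 cells, a human breast cancer line that lacks the estrogen and progesterone receptors and HER2 amplification. The cells carried a scrambled short hairpin RNA (shSC) or were labelled as carrying a hairpin against CHD4 (shCHD4), and were kept for 24 hours at 20% or 1% O2, with 2 libraries in each of the 4 groups. CHD4 is the ATPase of the NuRD complex, which remodels nucleosomes and removes acetyl groups from histones. The hypoxia-inducible factors (HIFs) are transcription factors that are stabilised at low oxygen and raise genes of glycolysis, angiogenesis and pH control, and the study asked whether CHD4 takes part in their activity. Per library, the values held 24947627 and 27884002 gene-assigned reads for shSC at 20% O2, 30102618 and 31903585 for shSC at 1% O2, 26152919 and 28272509 for shCHD4 at 20% O2, and 28784704 and 28153350 for shCHD4 at 1% O2. Between 16418 and 16861 genes had a read in a library, and 12645 genes had a mean normalised read count of at least 1 and were tested. Replicates correlated at r = 0.998 across genes, which are not independent replicates, and their counts differed by more than sampling noise (chi-square per degree of freedom 2.21 to 4.73). A principal component that separated the shSC from the shCHD4 label held 88.8% of the variance, and the component that separated 1% from 20% O2 held 7.57%. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

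CHD4 RNA was not lower in the libraries labelled shCHD4. Its normalised read count was 298.6 ± 0.47 (SD, n = 2) under shSC and 299.0 ± 7.9 under shCHD4 at 20% O2, and 278.9 ± 1.1 and 293.0 ± 8.64 at 1% O2. These values rest on 15255 to 16825 CHD4 reads per group. The log2 difference between labels was 0.0018 at 20% O2 (95% interval -0.086 to 0.089, adjusted p = 0.968) and 0.071 at 1% O2 (95% interval -0.017 to 0.158, adjusted p = 0.129). At 1% against 20% O2, CHD4 differed by -0.098 under shSC (adjusted p = 0.076, and -0.15 with adjusted p = 0.0106 with quantile normalization) and -0.029 under shCHD4 (adjusted p = 0.65), and 6710 of the 12645 genes, 53.1%, had a lower mean difference between labels than CHD4. Without shCHD4 20% O2 replicate 2 the difference at 20% O2 was -0.025. CHD4 passed the test as higher under the shCHD4 label with quantile normalization, by 0.11 at 20% O2 (adjusted p = 0.0201) and 0.23 at 1% O2 (adjusted p = 9.03e-05). After each library was centred on neighbouring genes, CHD4 passed as higher relative to them, by 0.18 (adjusted p = 0.00258) and 0.19 (adjusted p = 0.00194). The 40 genes nearest to CHD4 had median differences of -0.12 at 20% and -0.21 at 1% O2. So centring does not show CHD4 RNA itself to be higher. Over all alternatives its adjusted p ran from 0.00258 to 0.997 at 20% O2 and from 9.03e-05 to 0.529 at 1% O2. CHD4 protein was not measured here. Because the targeted RNA did not go with the label, each difference between shSC and shCHD4 is given as one between libraries with these labels, not as an effect of lower CHD4.

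**Figure D1:**
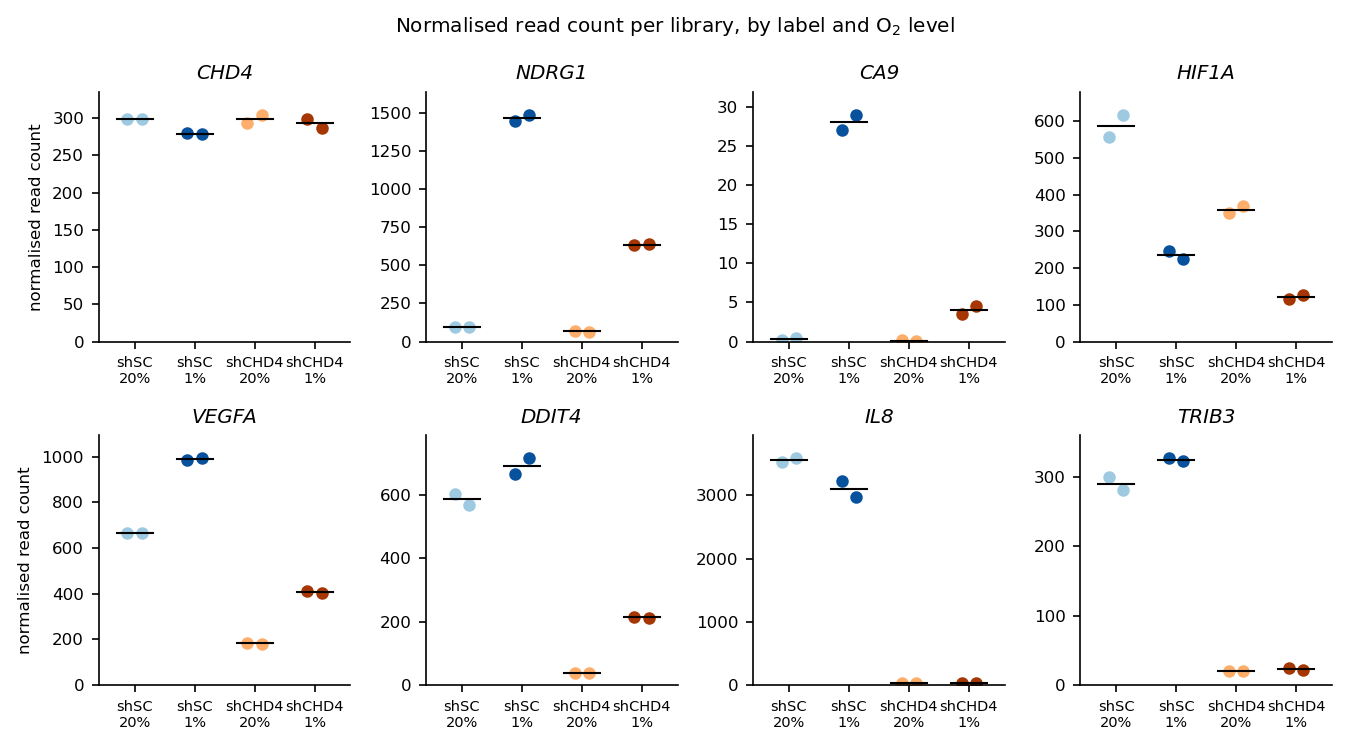
Normalised read counts of 8 genes in each library (points) and group means (lines), by hairpin label and O2 level, on linear axes that start at 0. CHD4 group means lie between 278.9 and 299.0, while IL8 differs from 3563 under shSC to 34.1 under the shCHD4 label at 20% O2.

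At 1% O2, control-labelled cells raised the HIF programme. CA9, the carbonic anhydrase that regulates pH outside the cell, was 34.1-fold higher (28.0 ± 1.4 against 0.345 ± 0.195 normalised counts, SD, n = 2, adjusted p = 1.15e-13). The pseudocount understates the folds of low genes, as for CA9, whose 20% O2 value rested on 18 reads. NDRG1, a commonly used hypoxia marker, was 15-fold higher (1470 ± 29.8 against 97.7 ± 0.758, adjusted p = 1.87e-21). PPFIA4 was 9.46-fold higher and C10orf10 8.65-fold. ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 8.12-fold higher, and MIR210HG, the host transcript of a hypoxia-induced microRNA, 7.74-fold. SPAG4, EGLN3 and TMEM45A, known HIF targets, were 7.72-fold, 7.6-fold and 6.31-fold higher, and FAM115C 6.29-fold. HIF1A itself, the gene of the HIF-1 alpha subunit, fell from 588.5 ± 42.3 to 235.5 ± 15.2 (SD, n = 2, 2.5-fold lower, adjusted p = 4.13e-12). Antisense transcripts overlap HIF1A and the strand setting of the counting is not given in the sources used here, so its value can include them.

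The largest falls under shSC were smaller than the rises. DIO2, the deiodinase that activates thyroid hormone, was 4.01-fold lower (5.501 to 0.991 normalised counts), and PTGES, which makes prostaglandin E2, 2.99-fold lower (148.5 to 49.3). The interferon-induced genes GBP4 (log2 change -1.20) and TRIM22 (-1.18), the antigen-presentation gene HLA-DMB (-1.16), the neuropeptide receptor VIPR1 (-1.15), the phosphodiesterase PDE7B (-1.14), the dynein gene DNAH2 (-1.12) and the neurotrophin BDNF (-1.07) followed. In all, 2197 genes rose and 2259 fell, 35.2% of those tested, and 106 of the rises and 13 of the falls were 2-fold or more.

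Of 49 tested HIF target genes, 46 rose over all genes tested and 47 adjusted over the list alone, with a median log2 change of 1.12. The HIF target list had camera adjusted p = 6.83e-54, and adjusted p = 0.0271 with an estimated correlation. NDRG1 was joined by BNIP3, a mitophagy receptor (5.58-fold), P4HA1, a collagen prolyl hydroxylase (4.53-fold), and LOX, the collagen crosslinking lysyl oxidase (4.01-fold, from 63.9 to 257.6). Of 23 glycolysis genes, 22 rose and 1, the phosphofructokinase gene PFKM, fell by either adjustment, over all genes or adjusted over the list alone. The glycolysis list had adjusted p = 7.62e-27, and adjusted p = 0.115 with an estimated correlation. PGK1 rose from 658.8 to 1877, LDHA, which makes lactate, from 1579 to 3978, ENO2 by a log2 change of 1.46 and HK2 by 1.04. Of 15 angiogenic and secreted factors, 14 rose by either adjustment (adjusted p = 2.89e-13, and adjusted p = 0.0271 with an estimated correlation), with IGFBP3 3.34-fold higher, ANGPTL4 as above, and TGFA and STC1 2.19-fold and 2.56-fold higher. Of 15 genes of collagen modification, 10 rose over all genes and 11 adjusted over the list alone, among them the lysyl hydroxylases PLOD2 (2.62-fold) and PLOD1 (2.12-fold). The collagen list had adjusted p = 3.31e-11, and adjusted p = 0.13 with an estimated correlation. Of 26 HIF targets described in breast cancer invasion and immune evasion, 22 rose and 2 fell by either adjustment. The invasion list had adjusted p = 3.16e-15, and adjusted p = 0.0285 with an estimated correlation.

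**Figure D2:**
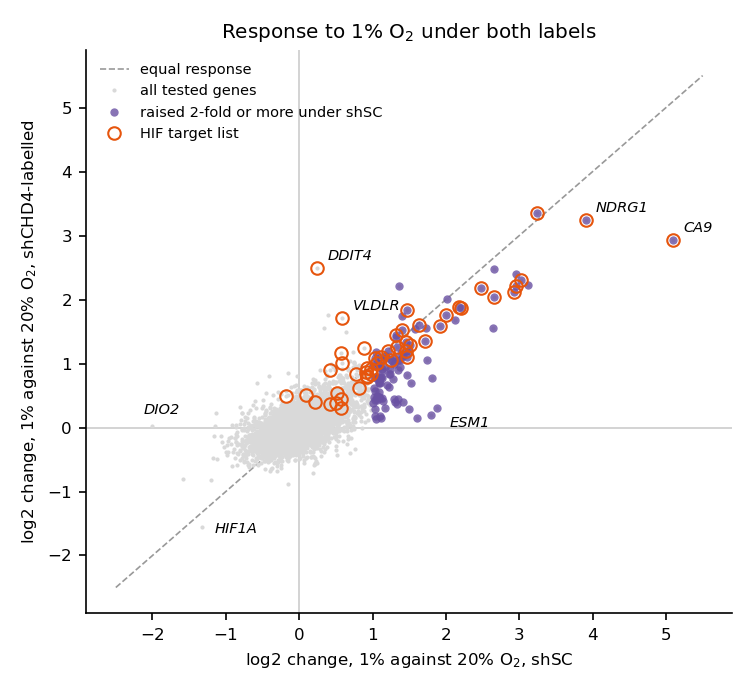
Log2 change at 1% against 20% O2 under shSC (horizontal) and under the shCHD4 label (vertical) for each tested gene (grey), the 106 genes raised 2-fold or more under shSC (purple) and the HIF target list (open circles). DDIT4 and VLDLR lie above the line of equal response, and CA9 and ESM1 lie below it. CA9 had 18 and 5 reads per group at 20% O2, and count tests called no interaction for it (adjusted p = 0.665 with edgeR and 0.736 with DESeq2). For ESM1, edgeR called none (adjusted p = 0.42).

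Other groups fell or rose with 1% O2 under shSC by smaller amounts. Of 34 cell cycle genes 23 fell, or 24 adjusted over the list alone. Those with the smallest p were the replication helicase subunits MCM5 (log2 change -0.78), MCM3 (-0.65), MCM2 (-0.60) and MCM6 (-0.48). The list had adjusted p = 7.89e-09, and adjusted p = 0.334 with an estimated correlation. Of 36 nuclear-encoded respiratory chain genes 17 fell, or 21 adjusted over the list alone, including the ATP synthase genes ATP5G1 (-0.54) and ATP5A1 (-0.31), ATP5B (-0.17) and the complex I genes NDUFS3 (-0.37) and NDUFV2 (-0.23). The respiratory list had adjusted p = 5.37e-05, and adjusted p = 0.514 with an estimated correlation, and the call of ATP5B ended without shSC 20% O2 replicate 1 (adjusted p = 0.086) and without a variance trend (adjusted p = 0.0636). Of 31 interferon-stimulated genes 20 fell and 2 rose, or 21 and 3 adjusted over the list alone, with IFIT1 at -0.95, IFIT2 at -0.86, HERC5 at -0.62 and IFIT3 at -0.56. The interferon list had adjusted p = 5.84e-07, and adjusted p = 0.0425 with an estimated correlation. Of 25 genes of the cholesterol list 12 fell and 1, INSIG1, rose by either adjustment, with DHCR7 at -0.48 and IDI1 at -0.40. The cholesterol list had adjusted p = 1.79e-05, and adjusted p = 0.153 with an estimated correlation.

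Of 21 genes of the ATF4 and amino acid response, 11 rose under shSC at 1% O2 and 12 did adjusted over the list alone, with PHGDH (log2 change 0.65) and PSAT1 (0.41) of serine synthesis, ASNS (0.58) of asparagine synthesis and VLDLR (0.58). Its test gave adjusted p = 0.00038, and adjusted p = 0.168 with an estimated correlation. Of 17 components of the HIF pathway 3 rose and 4 fell by either adjustment (adjusted p = 0.745), and the median (-0.021) and mean (0.075) of that list differed in sign. EGLN3 and EGLN1 (log2 change 0.77), the prolyl hydroxylases that mark HIF alpha subunits for degradation, rose, and HIF1A and EPAS1 (-0.42), which encode those subunits, fell. Of 14 NuRD genes 5 fell by either adjustment, namely RBBP4 (-0.39), MTA2 (-0.18), HDAC2 (-0.16), RBBP7 (-0.15) and CDK2AP1 (-0.15, adjusted p = 0.042). The NuRD list had adjusted p = 0.0382, and adjusted p = 0.191 with an estimated correlation. The NuRD call ended without shSC 1% O2 replicate 1 (adjusted p = 0.0838) and without shSC 20% O2 replicate 1 (adjusted p = 0.0775), within a range of 0.00292 to 0.191 over the alternatives. The RBBP7 call ended without shSC 1% O2 replicate 1 (adjusted p = 0.065) and without a variance trend (adjusted p = 0.0538). That of MTA2 ended after centring on neighbouring genes (-0.11, adjusted p = 0.0802).

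In cells labelled shCHD4, 1% O2 raised the same list of HIF targets. PPFIA4 was 10.2-fold higher, NDRG1 9.44-fold (66.9 ± 1.9 to 635.8 ± 6.51 normalised counts, SD, n = 2) and CA9 7.62-fold (0.0921 to 4.01). The 20% O2 values of CA9 and PPFIA4 under this label rested on 5 and 15 reads, so the pseudocount understates their folds. The order of these genes by fold, and the smaller CA9 fold than under shSC, therefore do not show a weaker rise of CA9. All 49 tested HIF targets rose by either adjustment (median log2 change 1.19, adjusted p = 1.62e-77, and adjusted p = 0.0271 with an estimated correlation). DDIT4, an inhibitor of mTORC1, was 5.62-fold higher, BNIP3 had a log2 change of 2.18 and P4HA1 of 1.89. HIF1A was 2.94-fold lower (359.7 ± 13 to 122.2 ± 7.46), followed by IQGAP2 (1.84-fold lower) and GBP4 (1.77-fold lower). Of 23 glycolysis genes 22 rose and 1, again PFKM, fell by either adjustment. The members with the smallest p were PGK1 (log2 change 1.29), LDHA (1.26), PFKFB3 (1.24) and HK2 (1.09). That list had adjusted p = 7.71e-35, and adjusted p = 0.0827 with an estimated correlation.

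Of the angiogenic factors 11 rose and 1, PGF, fell of 15 under the shCHD4 label by either adjustment. The angiogenic list had adjusted p = 5.03e-14, and adjusted p = 0.0271 with an estimated correlation. In the invasion list 21 rose and 2 fell of 26, or 22 and 2 adjusted over the list alone. The invasion list had adjusted p = 1.57e-18, and adjusted p = 0.0271 with an estimated correlation. In the collagen list 9 rose and 1 fell, or 10 and 1 adjusted over the list alone. The collagen list had adjusted p = 3.85e-10, and adjusted p = 0.13 with an estimated correlation. Of the 21 ATF4 genes 16 rose by either adjustment, with VLDLR at 1.71, ASNS at 0.91, the amino acid transporter gene SLC7A5 at 0.51 and PSAT1 at 0.50. The ATF4 list had adjusted p = 4.59e-13, and adjusted p = 0.0661 with an estimated correlation. Of 21 inflammatory genes 12 fell and 1 rose, or 13 and 1 adjusted over the list alone. CSF1 (-0.62), CXCL1 (-0.61) and IL8 (-0.40) fell and PTGS2 (0.60) rose. The inflammatory list had adjusted p = 0.000201, and adjusted p = 0.0827 with an estimated correlation.

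Cell cycle genes fell under the shCHD4 label too, 16 of 34, or 17 adjusted over the list alone. The cell cycle list had adjusted p = 1.28e-06, and adjusted p = 0.42 with an estimated correlation. CDC25A was at -0.43, CDC6 at -0.32, TYMS at -0.31 and MCM7 at -0.30, while MKI67, the member with the highest mean count over all libraries, differed by 0.029 (adjusted p = 0.702). The cell cycle call ended with a rotation test of direction (fry, adjusted p = 0.0586), within a range of 1.09e-07 to 0.42 over the alternatives. Cholesterol genes fell in 14 of 25 and rose in 1, again INSIG1, or 17 and 1 adjusted over the list alone. The cholesterol list had adjusted p = 2.32e-06, and adjusted p = 0.134 with an estimated correlation. Of 36 respiratory chain genes 7 fell by either adjustment (adjusted p = 0.0174, and adjusted p = 0.712 with an estimated correlation). The respiratory call also ended with fry (adjusted p = 0.301), without shCHD4 1% O2 replicate 1 (adjusted p = 0.16) and without shCHD4 20% O2 replicate 1 (adjusted p = 0.381), within a range of 0.000344 to 0.712. Of 31 interferon-stimulated genes 5 fell and 3 rose, or 9 and 3 adjusted over the list alone (adjusted p = 0.152), with ISG20 at 0.80, IRF9 at 0.69, SAMD9 at 0.21, OAS3 at -0.28 and DDX58 at -0.074 (adjusted p = 0.232). Without shCHD4 1% O2 replicate 2 the calls of OAS3 (adjusted p = 0.0775) and SAMD9 (adjusted p = 0.1) ended, as they did without shCHD4 20% O2 replicate 1 (adjusted p = 0.0508 and 0.0798). After centring on neighbouring genes OAS3 was at -0.12 and did not pass (adjusted p = 0.171), while DDX58 was at -0.15 and did (adjusted p = 0.028).

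In all, 1552 genes rose and 1351 fell with 1% O2 under the shCHD4 label, 23% of those tested, 63 and 1 of them by 2-fold or more. Of the 106 genes raised 2-fold or more under shSC, 91 also rose under the shCHD4 label, 49 by 2-fold or more, and of 13 lowered 2-fold or more, 7 also fell. Genes that rose in both numbered 1023 against 270 for independent lists, and those that fell 870 against 241, with no library shared between the comparisons. They do share each gene's estimate of the spread, so independent lists are not an exact expectation. The count of 2903 changed genes became 1343 without shCHD4 1% O2 replicate 1, 1459 without shCHD4 1% O2 replicate 2 and 1353 without shCHD4 20% O2 replicate 1. It was 1920 with no filter on low values and 1815 without a variance trend.

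At 20% O2, cells labelled shCHD4 had far lower RNA of inflammatory cytokines than shSC cells. IL8, the neutrophil chemokine CXCL8, was 103-fold lower (3563 ± 38.6 to 34.1 ± 0.77 normalised counts, SD, n = 2, adjusted p = 4.81e-24), and IL1B was 133-fold lower (276.0 to 1.59). The chemokines CXCL1 and CXCL2 were 136-fold and 120-fold lower, IL1A 95.1-fold, the complement gene C3 91.8-fold, IL6 88.7-fold (322.8 to 3.15), the granulocyte factor CSF3 68-fold, IL24 65-fold and the adhesion gene L1CAM 58.4-fold (151.3 to 2.11). All 21 tested members of the inflammatory and NF-kB list were lower, each by 2-fold or more and by either adjustment, with a median log2 difference of -3.86. The inflammatory list had adjusted p = 3.83e-16, and adjusted p = 0.0271 with an estimated correlation. CXCL1, CXCL2 and CXCL3 are similar in sequence, so reads can be split between them with error.

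Higher under the shCHD4 label at 20% O2 were IGFN1 (91.9-fold, from 0.0764 to 52.4, and only 4 reads under shSC), HSPA12A (32.4-fold), the coagulation factor gene F13A1 (27.8-fold), the nuclear pore gene NUP210 (22.6-fold), SCIN, which severs actin filaments (19.1-fold), ARHGAP30 (17.5-fold) and MEGF6 (14.2-fold). MAGEA12 (21.6-fold) and CSAG1 (16.4-fold) are neighbouring cancer-testis genes with near-identical copies, and their values are uncertain for that reason. A gene without an assigned name was among the 10 highest. In all 4674 genes were higher and 4885 lower, 75.6% of those tested, 623 and 1021 of them by 2-fold or more.

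The ATF4 and amino acid list was lower under the shCHD4 label in all 21 tested members at 20% O2 by either adjustment (median log2 difference -1.91). The ATF4 list had adjusted p = 7.73e-12, and adjusted p = 0.0732 with an estimated correlation. SESN2 was at -3.98, CHAC1, a glutathione-degrading enzyme, at -3.89, the pseudokinase gene TRIB3 14.1-fold lower and CTH, of cysteine synthesis, at -3.61. Of the 49 HIF targets 27 were lower and 11 higher by either adjustment (median -0.22). The HIF target list had adjusted p = 0.0406, and adjusted p = 0.544 with an estimated correlation. The HIF target call ended with quantile normalization (adjusted p = 0.0563, within a range of 0.000108 to 0.544). CA12 was 34.6-fold lower, DDIT4 15.3-fold, VLDLR at -2.26 and VEGFA, the vascular endothelial growth factor, 3.65-fold (666.4 to 182.2). Angiogenic factors were lower in 11 of 15 and higher in 3 by either adjustment, with STC1 at -2.98, IGFBP3 at -2.46 and EDN1 at -1.75. The angiogenic list had adjusted p = 0.00451, and adjusted p = 0.13 with an estimated correlation. Of the 26 invasion genes 19 were lower and 7 higher by either adjustment, with SLC7A11 at -2.59, CD274, which encodes PD-L1, at -2.19 and ITGA5 at -1.76 beside L1CAM at -5.87. The invasion list had adjusted p = 0.00482, and adjusted p = 0.173 with an estimated correlation. Of the HIF pathway genes 11 were lower and 3 higher of 17 by either adjustment. The HIF pathway list had adjusted p = 0.024, and adjusted p = 0.168 with an estimated correlation. VHL, the ubiquitin ligase subunit that recognises hydroxylated HIF, was 2.58-fold lower, SIAH2 at -1.47, EPAS1 at -1.36 and CREBBP at -0.97.

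Genes of the immediate early and heat shock list were lower in 15 of 20 and higher in 5 at 20% O2 under the shCHD4 label by either adjustment, with ATF3 at -3.95, DUSP1 at -2.96, MYC 6.2-fold lower and IER3 at -2.002. The immediate early list had adjusted p = 0.0045, and adjusted p = 0.302 with an estimated correlation. Mesenchymal genes were lower in 14 and higher in 4 of 18 by either adjustment, with the matrix genes THBS1 (-1.73) and CTGF (-1.84) and the cadherin CDH11 (-2.26) among them. The mesenchymal list had adjusted p = 0.00159, and adjusted p = 0.13 with an estimated correlation. Interferon-stimulated genes were lower in 19 and higher in 5 of 31 by either adjustment, with IFI27 at -4.06, BST2 at -3.05, XAF1 at -2.32 and IFIT2 at -1.32. The interferon list had adjusted p = 0.019, and adjusted p = 0.153 with an estimated correlation. Collagen modification genes were lower in 10 and higher in 2 of 15 by either adjustment. The collagen list had adjusted p = 0.0285, and adjusted p = 0.506 with an estimated correlation. The collagen call ended with quantile normalization (adjusted p = 0.0769, within a range of 0.000386 to 0.506). Of 13 epithelial and luminal genes 9 were lower and 3 higher by either adjustment (adjusted p = 0.12), with the transcription factor EHF 42.5-fold lower, CLDN7 at -2.66, KRT19 at -0.91 and the desmosomal gene DSP at 1.42.

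Cell cycle genes were higher under the shCHD4 label at 20% O2 in 27 of 34 and lower in 1, CENPF, or 27 and 2 adjusted over the list alone. The cell cycle list had adjusted p = 3.65e-06, and adjusted p = 0.437 with an estimated correlation. The cyclins CCNE1 and CCNE2 were at 2.26 and 1.70, MCM3 at 1.27 and TOP2A at 0.84. Of 9 replication-dependent histone genes, whose copies are near-identical, 8 were higher by either adjustment, with HIST1H2BK at 2.02, HIST1H2BD at 1.81, HIST1H1C at 1.71 and HIST1H2AC at 1.47. Only polyadenylated RNA was measured, so the histone values do not give total histone RNA at either O2 level. The histone list had adjusted p = 0.000438, and adjusted p = 0.154 with an estimated correlation. The group of neighbouring genes on chromosome 6 from GMNN to TRIM39, where these 4 lie, had a median of 0.39. Among 14 NuRD genes 6 were higher and 5 lower by either adjustment (adjusted p = 0.5), with RBBP4 at 0.74, RBBP7 at 0.49, HDAC2 at 0.37 and GATAD2B at -0.59. Glycolysis genes were lower in 12 and higher in 8 of 23 by either adjustment (adjusted p = 0.654).

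**Figure D3:**
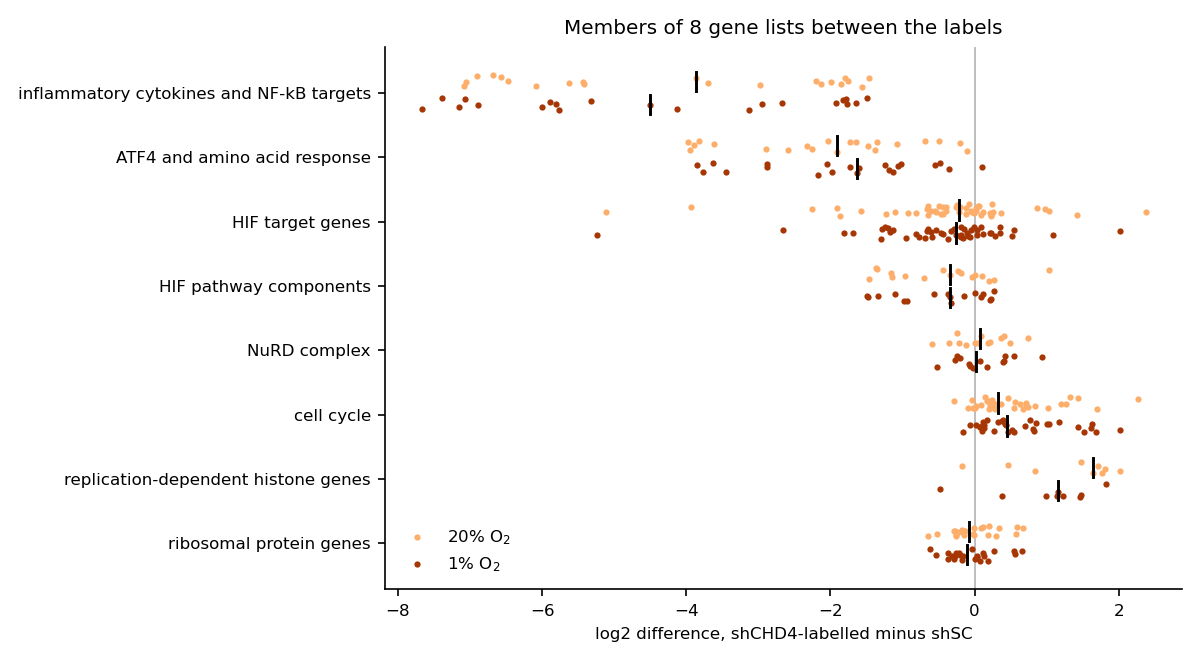
Log2 difference between the shCHD4 and shSC labels for each tested member of 8 gene lists at 20% (light) and 1% O2 (dark), with medians as black lines. The inflammatory list has medians of -3.86 and -4.50, and the histone list 1.64 and 1.15.

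At 1% O2, the comparison that bears on HIF activity at low oxygen, the labels differed in much the same genes. IL1B was 204-fold lower under the shCHD4 label (484.6 ± 10.5 to 1.88 ± 0.187 normalised counts, SD, n = 2), CXCL1 168-fold, IL1A 143-fold, CXCL2 135-fold, IL8 119-fold (3105 ± 181 to 25.7 ± 1.86), IL24 69.8-fold, C3 64.4-fold, IL6 64.1-fold, CXCL3 59.1-fold and CSF3 55.9-fold. IGFN1 was 70-fold higher, F13A1 34.7-fold, HSPA12A 34.5-fold, NUP210 23.5-fold, MAGEA12 22.7-fold and AMPH, which acts in endocytosis, 19.2-fold, followed by SCIN (log2 difference 4.15), CSAG1 (3.87), ARHGAP30 (3.87) and a gene without an assigned name. In all 4828 genes were higher and 4954 lower, 77.4% of those tested, 717 and 1083 of them by 2-fold or more. Genes higher at both O2 levels numbered 4226 against 1785 for independent lists, and genes lower at both 4394 against 1914, with no library shared, and the differences correlated across genes (r = 0.969, rho = 0.953). These comparisons share each gene's estimate of the spread and the same labelled cells, so independent lists are not an exact expectation.

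HIF targets were lower under the shCHD4 label at 1% O2 in 31 of 49 and higher in 9 by either adjustment (median log2 difference -0.25, against -0.22 at 20% O2). This comparison does not separate the response to 1% O2 from a difference already there at 20% O2, which the interaction below tests. The HIF target list had adjusted p = 0.0045, and adjusted p = 0.4 with an estimated correlation. CA12 was 37.7-fold lower, DDIT4 3.22-fold, VEGFA 2.43-fold (987.9 ± 6.92 to 406.9 ± 4.08, SD, n = 2) and LOX at -1.82. Angiogenic factors were lower in 11 of 15 and higher in 3 by either adjustment, with IGFBP3 at -3.15, STC1 at -2.13 and EDN1 at -1.83. The angiogenic list had adjusted p = 0.00341, and adjusted p = 0.13 with an estimated correlation. In the invasion list 19 of 26 were lower and 6 higher by either adjustment, with L1CAM at -5.66, CD274 at -2.20 and ITGA5 at -2.10. The invasion list had adjusted p = 0.000813, and adjusted p = 0.143 with an estimated correlation. Collagen modification genes were lower in 12 of 15 by either adjustment (adjusted p = 0.00121, and adjusted p = 0.302 with an estimated correlation). Glycolysis genes were lower in 13 and higher in 6 of 23 by either adjustment (adjusted p = 0.323). HIF pathway genes were lower in 11 and higher in 2 of 17 by either adjustment, with VHL 2.54-fold lower, SIAH2 at -1.49, EPAS1 at -1.48 and CREBBP at -0.98. The HIF pathway list had adjusted p = 0.0247, and adjusted p = 0.168 with an estimated correlation.

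All 21 tested inflammatory genes were again lower at 1% O2 under the shCHD4 label, by 2-fold or more and by either adjustment (median -4.50, adjusted p = 4.64e-16, and adjusted p = 0.0271 with an estimated correlation), among them ICAM1, a leukocyte adhesion molecule, 22.6-fold (1036 to 45.4). Of the 21 ATF4 genes 20 were lower and 1, SLC7A5, higher by either adjustment, with SESN2 at -3.85, TRIB3 13.7-fold lower, ATF3 at -3.63 and CTH at -3.44. The ATF4 list had adjusted p = 2.14e-10, and adjusted p = 0.0827 with an estimated correlation. Immediate early and heat shock genes were lower in 15 and higher in 5 of 20 by either adjustment, with EGR1 at -3.94, DUSP1 at -2.75, MYC 5.23-fold lower and IER3 at -1.83. The immediate early list had adjusted p = 0.00365, and adjusted p = 0.293 with an estimated correlation. Mesenchymal genes were lower in 14 and higher in 3 of 18 by either adjustment, with CTGF at -1.72, FN1 at -1.61 and THBS1 at -1.54. The mesenchymal list had adjusted p = 0.00074, and adjusted p = 0.13 with an estimated correlation. Of 13 epithelial genes 9 were lower and 3 higher by either adjustment (adjusted p = 0.105), with EHF 31.3-fold lower, CLDN7 at -2.75, KRT19 at -1.31 and DSP at 1.32. Interferon-stimulated genes were lower in 16 and higher in 11 of 31 by either adjustment (adjusted p = 0.553), with IFI27 at -4.18, BST2 at -2.86, XAF1 at -2.15 and SAMD9 at 1.17.

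Cell cycle genes were higher at 1% O2 under the shCHD4 label in 27 of 34 and lower in 1, KIF11, by either adjustment, with CCNE2 at 2.01, MCM3 at 1.63, KIF20A at 1.61 and MCM5 at 1.51. The cell cycle list had adjusted p = 4.24e-07, and adjusted p = 0.4 with an estimated correlation. Histone genes were higher in 8 of 9 and lower in 1, HIST1H1E, by either adjustment, with HIST1H2BK at 1.82, HIST1H1C at 1.48, HIST1H2BD at 1.46 and HIST1H2AC at 1.15. The histone list had adjusted p = 0.00204, and adjusted p = 0.18 with an estimated correlation. The neighbouring genes from GMNN to TRIM39 had a median of 0.37 at this O2 level. Respiratory chain genes were higher in 22 and lower in 6 of 36, or 23 and 6 adjusted over the list alone. The respiratory list had adjusted p = 0.0223, and adjusted p = 0.724 with an estimated correlation. NuRD genes were higher in 6 and lower in 4 of 14 by either adjustment (adjusted p = 0.48), with RBBP4 at 0.94, RBBP7 at 0.55, HDAC2 at 0.43 and GATAD2B at -0.52.

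Differences between the labels ran along chromosomes. Over 246 groups of 40 or more neighbouring autosomal genes, the SD of the group medians was 0.264 at 20% and 0.27 at 1% O2, against at most 0.116 and 0.119 in 1000 permutations of gene order (p = 0.001 by permutation, the smallest these can give). For 1% against 20% O2 the SD was 0.037 under shSC, against at most 0.041 in permuted order, and 0.042 under the shCHD4 label, against at most 0.034. On chromosome 13, 89.0% of 200 genes were higher under the shCHD4 label at 20% O2 (median log2 difference 0.71, and 0.76 at 1% O2), and on chromosome 8 the medians were -0.31 at both O2 levels. The genes from DUSP22 to TMEM14C on chromosome 6 had medians of 0.86 and 0.85, those from WDR67 to ZFP41 on chromosome 8 -0.84 and -1.06, and those from COL27A1 to SCAI on chromosome 9 -0.78 and -0.79. Beyond 0.3 in size were 52 group medians at 20% and 50 at 1% O2, 42 of them in the same direction at both. Their split depended on scaling, with 26 higher and 26 lower at 20% O2, but 46 higher and 14 lower with quantile normalization. After each library was centred on its neighbouring genes, 7180 of the called label differences at 20% O2 and 7501 at 1% O2 were called in the same direction.

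**Figure D4:**
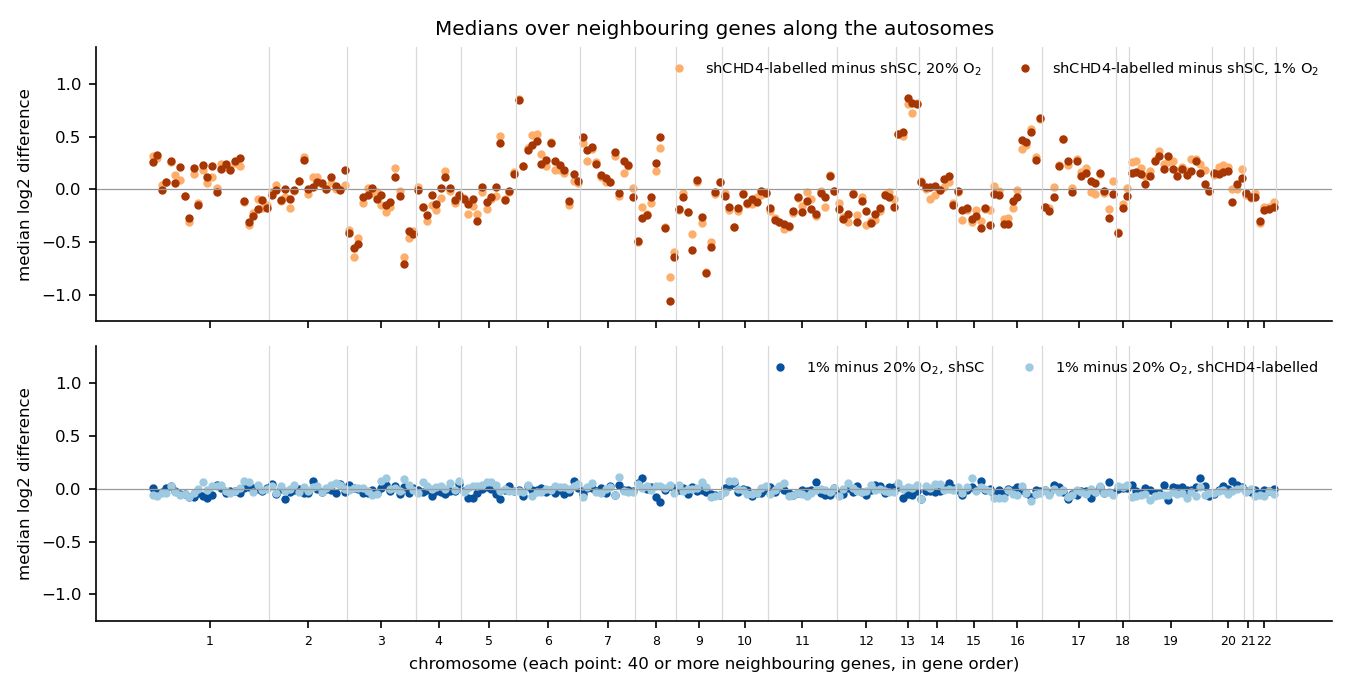
Median log2 difference of groups of 40 or more neighbouring genes in order along the autosomes, for the shCHD4 label against shSC (above) and 1% against 20% O2 (below), each point 1 group. The label medians spread with an SD of 0.264 at 20% O2, and the O2 medians under shSC with 0.037.

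The 106 genes raised 2-fold or more by 1% O2 under shSC were on balance lower at 1% O2 under the shCHD4 label. Their median log2 difference was -0.73 (-0.68 and -0.76 in the separate replicates, SD 0.055, n = 2), 77.4% were lower, and 74 passed the test as lower and 15 as higher. At 20% O2 the median of these genes was already -0.45, with 61 lower and 26 higher. The median rise with 1% O2 was 1.29 under shSC and 0.96 under the shCHD4 label, and the median interaction was -0.36 (-0.34 and -0.45 in the replicates), with 33 genes past the test with a smaller rise and 1 with a larger rise. Because the shSC libraries both picked and measured the genes, libraries with no label difference were simulated, and gave a median of -0.012 (-0.032 to 0.010 in 50 simulations) at 1% O2 and -0.025 (-0.064 to 0.014) for the interaction. Picked in 1 replicate and measured in the other, the median at 1% O2 was -0.55 for 103 genes and -0.58 for 121. The 63 genes raised 2-fold or more under the shCHD4 label had a median of -0.51 at 1% O2 and of -0.093 for the interaction, with 12 past the interaction test in each direction. The list of 49 HIF targets fixed beforehand had -0.25 and -0.074.

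The response to 1% O2 itself differed between the labels for a small part of the genes. DDIT4 rose little under shSC (585.8 to 691.5 normalised counts) and strongly under the shCHD4 label from a lower start (37.8 to 214.6), an interaction of 2.25 on the log2 scale (SE 0.069, adjusted p = 2.67e-13). DIO2 (2.02), PDE7B (1.37), NXPH4 (1.36), DMBT1 (1.27) and the transcription factor gene JDP2 (1.22) also had positive interactions. ESM1, an endothelial proteoglycan gene (1.98 to 8.56 under shSC, 0.145 to 0.297 under the shCHD4 label, interaction -1.57), ALOXE3 (-1.59), DHRS2 (-1.46), the collagenase MMP1 (104.9 to 296.9 against 26.3 to 32.2, -1.20) and DNAH11 (-1.10) had negative ones. CA9 had -2.16, but its 20% O2 values rested on 18 and 5 reads, and count tests on the recovered reads gave -0.88 (edgeR, adjusted p = 0.665) and -0.84 (DESeq2, adjusted p = 0.736) against a range of 8.82e-07 to 0.736 over all alternatives. The ESM1 call ended with edgeR (-1.08, adjusted p = 0.42, range 6.52e-05 to 0.42), and with no filter on low values NXPH4 and DNAH11 had adjusted p = 0.0589 and 0.0549, the highest of their alternatives.

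Among the fixed lists, interferon-stimulated genes had positive interactions in 9 of 31 genes, or 14 adjusted over the list alone, with IFIT2 at 0.86, IFIT1 at 0.79, OASL at 0.63, IFIT3 at 0.47 and DDX58 at 0.13 (adjusted p = 0.269). The interferon list had adjusted p = 3.95e-09, and adjusted p = 0.0285 with an estimated correlation. ATF4 genes had 5 positive interactions of 21, or 10 positive and 1 negative adjusted over the list alone, among them VLDLR (1.126), CHAC1 (1.02), ASNS (0.34) and SLC7A11 (0.42), and SLC7A5 was at 0.21 (adjusted p = 0.0508). That list had adjusted p = 6.03e-06, and adjusted p = 0.13 with an estimated correlation. The call of ASNS ended without shCHD4 1% O2 replicate 1 (adjusted p = 0.075). That of SLC7A11 ended without shCHD4 1% O2 replicate 1 (0.0744), shSC 1% O2 replicate 2 (0.0758), shCHD4 20% O2 replicate 1 (0.0923) or shSC 20% O2 replicate 2 (0.0583). SLC7A5 passed without shSC 20% O2 replicate 2 (0.0394). Inflammatory genes had 5 negative and 2 positive of 21, or 13 and 4 adjusted over the list alone, with ICAM1 at -0.80, RELB at -0.54, NFKB2 at -0.36, IL11 at 0.71 and IL8 at -0.20 (adjusted p = 0.127), which was 0.47 with quantile normalization (adjusted p = 0.000467). Their test gave adjusted p = 0.000202, and adjusted p = 0.0827 with an estimated correlation. For HIF targets 7 were positive and 9 negative of 49, or 8 and 14 adjusted over the list alone (adjusted p = 0.105), with VLDLR, DDIT4 and VEGFA (0.59) positive, NDRG1 (-0.67) negative and LDHA at -0.068 (adjusted p = 0.622). The median (-0.074) and mean (-0.059) of that list were negative, and a rotation test of direction (fry) had adjusted p = 0.929.

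Collagen genes had 2 negative interactions of 15, P4HA1 (-0.29) and PLOD1 (-0.37), or 6 adjusted over the list alone, with PLOD2 at -0.23 (adjusted p = 0.0565) and P4HB at -0.20 (adjusted p = 0.0601). The collagen list had adjusted p = 2.75e-05, and adjusted p = 0.22 with an estimated correlation. Cell cycle genes had 5 positive and 1 negative of 34, or 11 and 1 adjusted over the list alone, with MCM5 at 0.49, MCM3 at 0.36, PCNA at 0.30, CCNE1 at -0.57 and MKI67 at -0.022 (adjusted p = 0.903). The cell cycle list had adjusted p = 0.00155, and adjusted p = 0.618 with an estimated correlation, and its call ended with fry (adjusted p = 0.379) and without shSC 1% O2 replicate 1 (adjusted p = 0.216), within a range of 4.02e-08 to 0.618. Of 9 histone genes 6 had negative interactions adjusted over the list alone, among them HIST1H2BK (-0.20), HIST1H2BD (-0.35), HIST1H2BC (-0.63) and HIST1H4H (-0.66), whose adjusted p over all genes ran from 0.0601 to 0.0845. The histone list had adjusted p = 0.00121, and adjusted p = 0.168 with an estimated correlation. Single libraries decided several of these calls. Without shCHD4 1% O2 replicate 1, those of P4HA1, MCM3 and CCNE1 ended (adjusted p = 0.0824, 0.0666 and 0.0528), and without shCHD4 1% O2 replicate 2 those of P4HA1, MCM3, PCNA and CCNE1 (0.101, 0.0948, 0.176 and 0.146). Without shSC 1% O2 replicate 1, MCM3 and PCNA did not pass (0.0878 and 0.132), and without shSC 1% O2 replicate 2 P4HA1 and CCNE1 did not (0.0644 and 0.0588) while HIST1H2BD and HIST1H2BK did (0.0481 and 0.0416). Without shCHD4 20% O2 replicate 1, P4HA1, MCM3 and CCNE1 did not pass (0.0895, 0.0506 and 0.133), nor MCM3 and PCNA without shCHD4 20% O2 replicate 2 (0.0701 and 0.133). Without shSC 20% O2 replicate 1, P4HB and HIST1H4H passed (0.0261 and 0.0437), and without shSC 20% O2 replicate 2 PLOD2 passed (0.0236) while PCNA and CCNE1 did not (0.0531 and 0.055).

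Other alternatives changed interaction calls of these lists too. With no filter on low values OASL (adjusted p = 0.0635), ASNS (0.0722), SLC7A11 (0.178), P4HA1 (0.086), PLOD1 (0.059), MCM3 (0.18), PCNA (0.146) and CCNE1 (0.124) did not pass. Without a variance trend OASL (0.0582), ASNS (0.116), SLC7A11 (0.206), P4HA1 (0.135), PLOD1 (0.0968), MCM3 (0.213), MCM5 (0.0625), PCNA (0.195) and NFKB2 (0.0716) did not. After centring on neighbouring genes the calls of P4HA1 (0.165), MCM3 (0.106), PCNA (0.0806) and SLC7A11 (0.0611) ended, while PLOD2 (0.0359), HIST1H2BK (0.0297) and IL8 (-0.36, 0.0278) passed. That of P4HA1 also ended with quantile normalization (0.0736), and those of CCNE1 and SLC7A11 with DESeq2 (0.134 and 0.172). SLC7A5 passed with a minimum mean of 5 (0.0452), quantile normalization (0.00879), edgeR (0.0439) and DESeq2 (0.0312). PLOD2 passed with median-ratio scaling (0.0479) and DESeq2 (0.049), and P4HB with DESeq2 (0.0315).

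In all, 280 interactions were positive and 271 negative, 551 genes or 4.36% of those tested. The count rested on single libraries. It was 265 without shCHD4 1% O2 replicate 1, 254 without shCHD4 1% O2 replicate 2, 320 without shSC 1% O2 replicate 1, 326 and 362 without shCHD4 20% O2 replicate 1 and replicate 2, and 990 without shSC 20% O2 replicate 1. It was 155 with no filter on low values and 155 without a variance trend. With genes changed by known amounts in simulated libraries, 76% of interactions of 1.5-fold and 96% of 2-fold were recovered, so smaller interactions than that were often not detectable at this depth and number of libraries.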

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

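The tests of selection, scaling and chromosome regions for the genes raised by 1% O2 were chosen after the result was seen. The response to 1% O2 differed between libraries labelled shSC and shCHD4, tested as an interaction, for 551 genes. This count became 254 and 265 without shCHD4 1% O2 replicate 2 and replicate 1, 320 without shSC 1% O2 replicate 1, 326 and 362 without shCHD4 20% O2 replicate 1 and replicate 2, and 990 without shSC 20% O2 replicate 1. CHD4 RNA was not lower under the shCHD4 label, so these are differences between labels.

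Interactions in the positive direction were 2.25 for DDIT4, 2.02 for DIO2, 1.37 for PDE7B, 1.36 for NXPH4, 1.27 for DMBT1 and 1.22 for JDP2. DIO2 fell from 5.501 to 0.991 normalised read counts under shSC and was 2.07 at both O2 levels under the shCHD4 label. Interactions in the negative direction were -2.16 for CA9, -1.59 for ALOXE3, -1.57 for ESM1, -1.46 for DHRS2, -1.20 for MMP1 and -1.10 for DNAH11. Count tests on the recovered reads ended the calls of CA9 (edgeR adjusted p = 0.665, DESeq2 adjusted p = 0.736) and ESM1 (edgeR adjusted p = 0.42), within ranges of 8.82e-07 to 0.736 and 6.52e-05 to 0.42 over their alternatives.

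Lists whose interaction passed the camera test were interferon-stimulated genes (adjusted p = 3.95e-09), the ATF4 and amino acid response (6.03e-06), collagen modification (2.75e-05), inflammatory genes (0.000202), histone genes (0.00121), cell cycle (0.00155), the respiratory chain (0.00777) and the invasion list (0.0106). With an estimated correlation only the interferon list passed (adjusted p = 0.0285), and the others had 0.13, 0.22, 0.0827, 0.168, 0.618, 0.679 and 0.197 in the order of their camera p. That version also has fewer degrees of freedom, so these losses do not measure correlation alone. Interferon, ATF4, cell cycle and respiratory chain genes had positive medians (0.22, 0.17, 0.081 and 0.07), and collagen, inflammatory, histone and invasion genes negative ones (-0.14, -0.22, -0.30 and -0.041). In the respiratory chain 1 gene of 36 passed over all genes. Its call ended with fry (adjusted p = 0.379), without shCHD4 1% O2 replicate 2 (0.105), without shSC 1% O2 replicate 1 (0.0568), without shCHD4 20% O2 replicate 2 (0.292) and without shSC 20% O2 replicate 1 (0.256). For cell cycle the call ended with fry (0.379) and without shSC 1% O2 replicate 1 (0.216). In the invasion list 1 gene was positive and 5 negative of 26, or 2 and 8 adjusted over the list alone, and its call ended with quantile normalization (0.204) and without shSC 1% O2 replicate 2 (0.0507).

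The 106 genes raised 2-fold or more by 1% O2 under shSC had a median log2 difference of -0.73 between labels at 1% O2, with 74 past the test as lower under the shCHD4 label and 15 as higher. Noise of single libraries in picking the genes is argued against as the whole cause. The median in the replicate not used for picking was -0.55, below the lowest of -0.032 simulated with no label difference. Neither check covers genes picked because their response truly differed between labels, or a deviation shared by libraries of 1 culture. The 63 genes picked under the shCHD4 label instead had a median of -0.51 at 1% O2. Their median interaction was -0.093, with 12 past the test in each direction, against -0.36 with 33 smaller and 1 larger for the 106 genes. Chromosome regions and scaling are argued against as well, with medians of -0.70 after centring on neighbouring genes and -0.68 after quantile normalization. A weaker HIF response in the cells labelled shCHD4 is a hypothesis for part of it, but the fixed list of HIF targets had an interaction median of only -0.074, with no call (adjusted p = 0.105), and the median of the 106 genes was already -0.45 at 20% O2, with 61 lower and 26 higher. Since CHD4 RNA was not lower under the shCHD4 label, these data do not tie the difference to CHD4, and another difference between the cell populations may give it, which was not tested.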

How the results depend on the processing

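Centring on neighbouring genes and the use of count tests on recovered reads were chosen after the data were seen. Of these, edgeR had been named beforehand for a table of raw counts. Over the alternatives, 5336 values of the 265 named gene results kept direction and side of the threshold, 136 lost the call, 18 gained it and 9 reversed, and for the 61 called list tests 720 kept it and 73 lost it. Most named genes were picked for large changes or small p in these data, so that most kept the call is largely given by that choice. The 136 include calls lost to the 2-fold minimum, which ends calls by construction. With a 2-fold minimum the counts were 119 and 64 for 1% O2 under shSC and the shCHD4 label, 1644 and 1800 for the label at 20% and 1% O2, and 25 for the interaction, fewer by construction. With no filter on low values the counts for O2 under the shCHD4 label and the interaction were 1920 and 155, and without a variance trend 1815 and 155. Leaving out 1 library, which leaves a group with 1 library assumed to vary like the others, gave 3025 to 4359 for O2 under shSC, 1343 to 3472 under the shCHD4 label (1343 and 1459 without shCHD4 1% O2 replicate 1 and replicate 2, 1353 without shCHD4 20% O2 replicate 1), 8791 to 9589 and 8928 to 9958 for the label at 20% and 1% O2, and 254 to 990 for the interaction (265 and 254 without shCHD4 1% O2 replicate 1 and replicate 2, 320 without shSC 1% O2 replicate 1, 326 and 362 without shCHD4 20% O2 replicate 1 and replicate 2, 990 without shSC 20% O2 replicate 1). CHD4 differed between labels by 0.23 at 1% and 0.11 at 20% O2 with quantile normalization, and at 20% O2 by -0.025 (without shCHD4 20% O2 replicate 2) to 0.029 with 1 library left out. After regional centring CHD4 differed by 0.19 at 1% and 0.18 at 20% O2, relative to its neighbours and not in RNA level. The median of the hypoxia-induced genes at 1% O2 was -0.59 with a pseudocount of 0.1, -0.86 with a minimum mean of 5, -0.51 for genes picked under the shCHD4 label, -0.25 for the HIF target list, -0.30 with no minimum change, -0.55 and -0.58 when picked in 1 replicate and measured in the other, and -0.78 to -0.53 with 1 library left out. Their median interaction was -0.093 for genes picked under the shCHD4 label, -0.074 for the HIF list, -0.14 with no minimum change and -0.29 when picked in replicate 2. With an estimated correlation 10 list tests passed. Groups of neighbouring genes beyond 0.3 at 20% O2 were 26 higher and 26 lower, 27 and 23 with median-ratio scaling and 46 and 14 with quantile normalization. IL8 had an interaction of 0.47 with quantile normalization. MKI67 for O2 under the shCHD4 label was -0.01 with quantile normalization and -0.027 to 0.084 with 1 library left out, and its interaction 0.087 with quantile normalization, 0.005 with regional centring and -0.077 to 0.034 with 1 library left out, the reversals being those without shCHD4 1% O2 replicate 1 or shCHD4 20% O2 replicate 1 for O2, and without shCHD4 1% O2 replicate 2, shSC 1% O2 replicate 2 or shCHD4 20% O2 replicate 2 for the interaction. Except for the 2-fold minimum the cause was not tested.

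Libraries with the same number are known to share only that number. Correlations of their deviations ran from -0.121 to 0.124. They were 0.0703 and 0.124 for pairs at the same O2 level, and -0.121 and -0.0842 for pairs with the same label. Such values do not settle whether anything else was shared. With the replicate block the counts were 4370, 2795, 9536, 9755 and 536 and 61 list tests passed. Fitting only the groups compared was not run for the interaction, which needs all of them. No scaling moved the median of all genes by over 0.1 or the split of higher and lower calls by over 10 points. Depth limits low genes most, as for CA9 with 18 and 5 reads per group at 20% O2.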

Other observations

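The tests on the CHD4 result and on a cell population with other chromosome copies were chosen after the results were seen. Those of scaling and GC content for neighbouring genes were chosen before their own results were known. The analysis of neighbouring genes was itself chosen after the data were seen. Some lists have not been described above. With 1% O2, glycogen metabolism genes rose in 7 of 11 under shSC by either adjustment (adjusted p = 0.000229, and adjusted p = 0.0827 with an estimated correlation). Under the shCHD4 label 8 of them rose, or 8 with 2 falls adjusted over the list alone (adjusted p = 0.000201, and adjusted p = 0.0827 with an estimated correlation). Unfolded protein response genes rose in 9 of 18 and fell in 2 under shSC, or 9 and 3 adjusted over the list alone (adjusted p = 0.0176, and adjusted p = 0.27 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.108, range 0.00476 to 0.27). Of the same genes 6 rose and 1 fell under the shCHD4 label (adjusted p = 0.105). Mesenchymal genes rose in 7 and fell in 3 of 18 under shSC by either adjustment (adjusted p = 0.0045, and adjusted p = 0.153 with an estimated correlation), a call that also ended with quantile normalization (adjusted p = 0.103, range 0.000142 to 0.153). Under the shCHD4 label 8 mesenchymal genes rose and 1 fell, or 9 and 1 adjusted over the list alone (adjusted p = 2.75e-05, and adjusted p = 0.0827 with an estimated correlation). Epithelial genes rose in 6 and fell in 2 of 13 under shSC, or 6 and 4 adjusted over the list alone (adjusted p = 0.0488, and adjusted p = 0.204 with an estimated correlation). The epithelial call under shSC ended without shSC 1% O2 replicate 2 (adjusted p = 0.106) and without shSC 20% O2 replicate 2 (adjusted p = 0.0833). Under the shCHD4 label 5 epithelial genes rose and 2 fell, or 6 and 2 adjusted over the list alone (adjusted p = 0.024, and adjusted p = 0.168 with an estimated correlation).

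Neuronal genes rose in 3 of 8 with 1% O2 under the shCHD4 label by either adjustment (adjusted p = 0.035, and adjusted p = 0.192 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.0793, range 0.00404 to 0.192). At 20% O2 5 of them were lower and 1 higher between labels (adjusted p = 0.104). Targets of p53 were lower in 9 and higher in 5 of 18 between labels at 20% O2, or 9 and 6 adjusted over the list alone (adjusted p = 0.301), in a line with mutant p53. Ribosomal protein genes were lower in 12 and higher in 8 of 24 between labels at 20% O2 by either adjustment (median -0.079, adjusted p = 0.873). Of the other cell types that were looked for, 5 leukocyte and endothelial markers were abundant enough to test. Of these 2 were lower and 1 higher between labels at 20% O2, or 3 and 1 adjusted over the list alone (adjusted p = 0.661). Of 2 muscle genes tested 1 was higher and 1 lower, and 3 fibroblast markers were higher at both O2 levels, by either adjustment.

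CHD4 RNA was not lower under the shCHD4 label, and passed the test as higher with quantile normalization. After centring, CHD4 passed as higher relative to its neighbouring genes, which were themselves lower on balance, and not in RNA level. Exchanged labels with a hairpin that lowers CHD4 RNA by a log2 change of 0.5 or more would need CHD4 to be higher under the shCHD4 label by as much. The upper end of the CHD4 interval was 0.158 at 1% O2 and 0.089 at 20% O2, and the largest difference in any alternative was 0.23. This assumes that both cell populations had the same CHD4 level without a hairpin, which was not measured. At 20% O2, 75.6% of tested genes differed between the labels. Without that assumption, an exchange or a fall that was offset by another starting level stays open. More copies of the region of CHD4 on chromosome 12 would need its 40 nearest genes to be higher, and their median was -0.12 (SE 0.084) at 20% and -0.21 (SE 0.105) at 1% O2. Too few reads would leave room for a large fall, and the interval reached no lower than -0.086. Exchanged labels with a hairpin that lowers CHD4 RNA by less or not at all stay open, since the difference of 0.071 at 1% O2 is also expected of such a hairpin with correct labels. What also stays open, as untested, is that the hairpin lowered CHD4 protein without its RNA, that it was lost from or never in these cells, or that the libraries are of other cells than their labels say.

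Neighbouring genes differed together between the labels. Scaling between libraries is argued against as the source of their spread by an SD of the group medians of 0.266 at 20% O2 after quantile normalization, against 0.264 without it. It does bear on their direction, since groups beyond 0.3 went from 26 higher and 26 lower to 46 and 14. GC content and gene length are argued against by an SD of 0.261 after their trends were removed, against at most 0.109 for those values in permuted order. A cell population with other chromosome copies needs long stretches, and medians of adjoining groups correlated at 0.71 at 20% O2, above the highest of 0.265 in permuted order. An action of the hairpin over long stretches of chromatin would give this too. A subpopulation or derived line with other chromosome copies among the cells labelled shCHD4 and such an action cannot be told apart here, since no DNA was measured, and both stay open.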
